A study of Folsomia candida with 4 samples.

How the data were processed

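The series holds 4 two-colour Agilent arrays hybridised with RNA of 8 jars of Folsomia candida of the Berlin strain, 4 heat-shocked and 4 reference, with 500 ng of RNA per labelling per the labels. Each scanner file lists 10806 spots, of which 10262 carry 5131 probes of 60 nt at 2 spots each and 544 are controls. Per the file headers, the deposited intensity of each channel was extracted with Agilent Feature Extraction 9.1.3.1 as mean spot signal and median local background, and a processed signal was background-subtracted and dye-normalized by the same software. The deposited LogRatio column is a log10 ratio of processed red (Cy5) over processed green (Cy3), per the file headers; it equalled that ratio within 0.001 for 79.2% of probe spots. A table of the authors' processed values is in log2 units by its values; the submitters' processing notes name limma 2.14.5 and give no steps. Its columns correlated with the ratios computed here, turned as heat shock over reference, at r from 0.993 to 0.997 across probes, with slopes of 1.05 to 1.10 and medians of 0.0114, -0.0117, 0.00637 and 0.000164 for arrays 1 to 4; its normalization and centring stay unstated.

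Mean signals were corrected with normexp (offset 50) on the median local background and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots with outlier marks, 8 in all, were left out, saturated spots were kept, and the spots of a probe were averaged. The ratios of arrays 2 and 4 were turned so that every value reads heat shock over reference, through a design of 1 and -1. A moderated linear model (lmFit and eBayes, two-sided, residual degrees of freedom 3, prior 1.50) was fitted over the 4 arrays with Benjamini-Hochberg adjustment, at a threshold of 0.05. A second model added a dye column. Levels per jar are channel signals after loess and Aquantile, open to dye bias in any 1 jar. Fold changes of a probe that was saturated, or not well above background, on every array of a group are bounds.

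The fit was tested on simulated data for this comparison, in 10 draws on the 5131 probes, each with 200 changed ones. It recovered 83.5% of 2-fold and 93.7% of 4-fold changes, with 6.64% of calls false and 0 of the wrong sign. Changes were planted among the brighter probes only, as many up as down, with independent noise. These rates therefore do not carry over to dim probes or to data with fewer changes. Arrays 1 and 2 shared slide 1 and arrays 3 and 4 slide 2, so slide was used as a block and values were given within slides. Position on the slide followed the dye orientation and cannot be told apart from it.

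The rule for named genes, set before the data were examined, took the 12 largest rises and falls among described genes, members of chaperone lists that passed, and for probes without a description at most 2 that rose and 2 that fell by ID, largest change first. All 5131 descriptions are "Unknown", each name equals its probe ID, and 0 IDs could be matched to the reference gene table (assembly ASM221717v1), so 2 rising probes are named, and a fall is given only for the probe nearest the threshold. The planned tests on gene lists, and the summary of several probes per gene, were not run for the same reason. The gene fit equals the probe fit. No coordinates are given, since no genome sequence was at hand. Alternatives covered background correction, normalization, dim probes, outlier spots, the dye column, the prior, separate channels, the authors' table, slide, array weights and arrays left out. Probe sequences were searched and compared with Python 3.11.15, Biopython 1.88, scipy 1.17.1 and blastn 2.17.0, and plots drawn with matplotlib 3.10.9.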

Results

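Gene expression after heat shock was measured in the soil springtail Folsomia candida on 4 two-colour Agilent arrays, each carrying 5131 probes. Every array held RNA from 1 heat-shocked jar and RNA from 1 reference jar, and no jar was used more than once, so 8 RNA samples gave 4 independent ratios. Each jar held about 30 animals of 25 days old that had spent 2 days in soil at 20 C. The treated jars then spent 30 min at 30 C. Heat shock RNA carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4. Median spot signals ran from 93.9 to 146 in Cy3, over local backgrounds of 48 to 51, and from 179 to 220 in Cy5, over local backgrounds of 89 to 92. Between 63.0% and 73.6% of probe spots were well above background per channel, and 3089 probes (60.2%) were so in all 8 channels. The files describe every probe as unknown, so results are given by probe ID, and families of stress genes could not be tested by name. The number of arrays limits the precision.

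The comparison of heat-shocked with reference jars asked which transcripts change within 30 min at 30 C. In these animals the called response was a rise: 17 of 5131 probes passed an adjusted p of 0.05 (limma, n = 4 arrays), all of them higher after heat shock, and each was higher on all 4 arrays. Probe Fcc02261 rose by 4.91 on the log2 scale (SE 0.09, adjusted p = 0.000675), with log2 ratios of 4.88, 5.06, 5.05 and 4.65 on arrays 1 to 4. Its signal was saturated in the heat shock channel of all 4 arrays, so under this normalization the rise was at least 30.1-fold; with median centring in place of loess its log2 fold change was 4.53. Probe Fcc01918C1 rose with a log2 fold change of 3.62 (SE 0.11, adjusted p = 0.00292) and log2 ratios of 3.52, 3.97, 3.62 and 3.35. It was well above background in all 4 heat-shocked jars and in none of the 4 reference jars, which makes its rise at least 10.3-fold under the same processing. Since both are bounds, the 2 rises have no order: Fcc02261 had the larger fitted value here, and Fcc01918C1 had the larger one with offset 0 (5.72 against 4.85) and with Agilent's processed ratios (6.25 against 4.92). Both bounds set the mean normalized log2 signal of the brighter group against that of the dimmer, with a dim signal raised to the lowest detected signal of its array. The SE and adjusted p of both probes also rest on these limited signals, so they can understate the spread between jars.

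**Figure D1:**
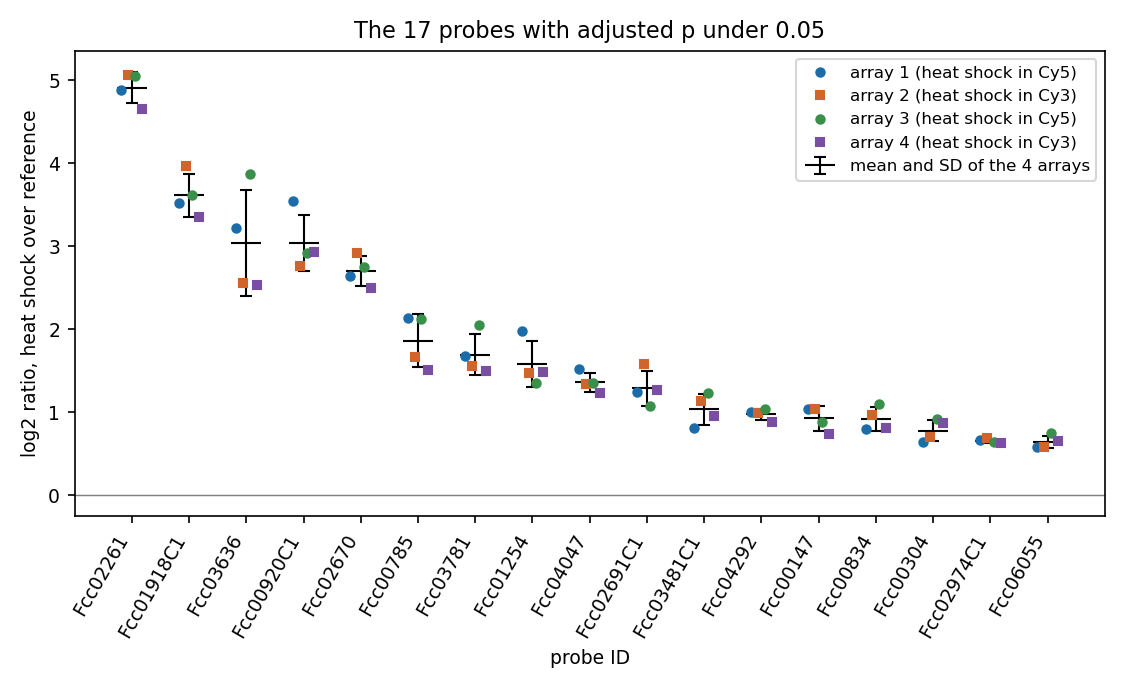
Log2 ratio of heat shock over reference (vertical axis) for the 17 probes that rose (horizontal axis, by probe ID), with 1 point per array, coloured by array, circles where heat shock RNA carried Cy5 and squares where it carried Cy3. Bars give the mean and SD of the 4 arrays, and every point lies above 0.

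The 17 rising probes covered a wide range of sizes. Of these, 4 rose at least 8-fold, 11 at least 2-fold and 6 less than 2-fold, with a median of 2.57-fold and a smallest rise of 1.56-fold. The SD over the 4 arrays had a median of 0.18 log2 units among them and reached 0.64. Of the 17 probes, 15 were well above background in all 8 channels. No rising probe aligned over 30 bases or more to another probe of the array, but only 6 of all 5131 probes did. The 17 rises were measured with separate sequences, which does not tell whether each reports a separate transcript.

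Large and repeated changes were one-sided whether or not they passed the test. At least 2-fold higher levels on all 4 arrays were seen for 19 probes, of which 10 passed the adjusted p and 9 did not, and at least 2-fold lower levels on all 4 arrays for 0 probes. With 3 of the 4 arrays asked for, the counts were 33 higher and 0 lower. Changes of any size had 1 sign on all 4 arrays for 15.9% of probes, 415 higher and 400 lower, against the 12.5% that chance gives; loess centres each array near 0, so that balance is no result. At an unadjusted p under 0.05 (limma) there were 444 probes, 253 higher and 191 lower.

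No probe was called lower (limma, 0 of 5131, against 191 at an unadjusted p under 0.05). The probe with the smallest adjusted p among those with lower means, Fcc01313C1, had a log2 fold change of -0.97 (SE 0.10, adjusted p = 0.0612) with log2 ratios of -0.69, -0.91, -1.08 and -1.21. It passed the threshold in 4 of the alternative analyses and not in the others. Agilent's own processed ratios called 12 probes higher and 4 lower, against 17 and 0 here.

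The count of 17 rested on all 4 jar pairs. It was 2 without array 1, 5 without array 2, 4 without array 3 and 3 without array 4, while Fcc02261 passed the threshold each time and Fcc01918C1 missed it without array 1 (adjusted p = 0.0517). Within slides, each of which held both dye orientations, the 17 probes had median log2 ratios of 1.43 on slide 1 and 1.29 on slide 2, and with slide as a fixed block 3 probes passed.

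The 4 jar pairs differed in how many probes had ratios of at least 2-fold, a count per array that includes measurement noise. These probes numbered 117 (109 higher and 8 lower) on array 1, 106 (43 and 63) on array 2, 349 (207 and 142) on array 3 and 174 (75 and 99) on array 4. Across probes, which are not independent replicates, heat shock over reference ratios correlated between arrays with Pearson r from -0.39, for arrays 2 and 3, to 0.52, for arrays 3 and 4. The duplicate spots of a probe correlated with r from 0.882 to 0.975 within an array.

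**Figure D2:**
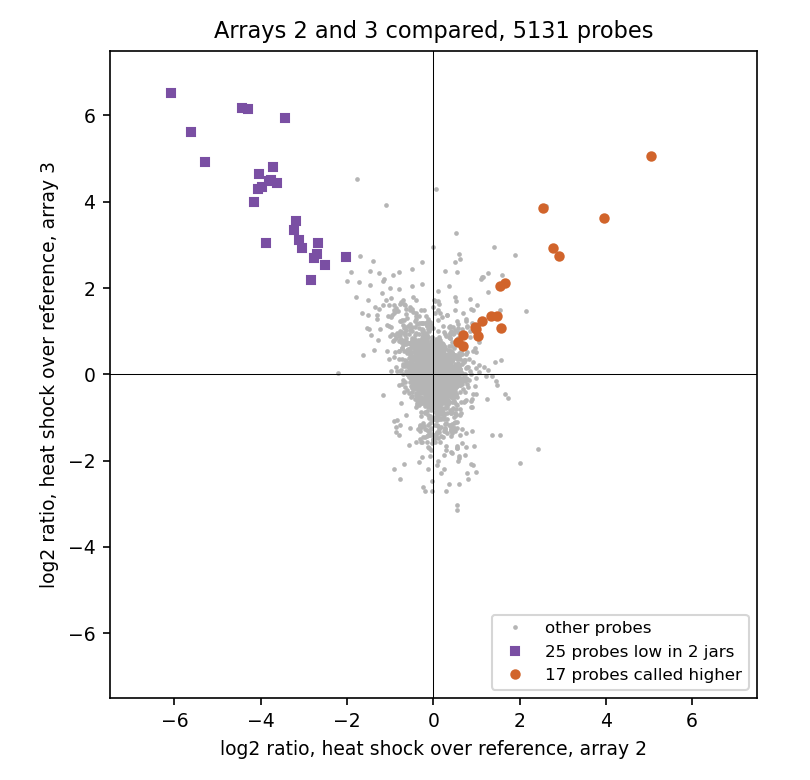
Log2 ratio of heat shock over reference on array 2 (horizontal axis) against array 3 (vertical axis), with 1 point per probe for 5131 probes. The 17 rising probes (orange circles) lie above 0 on both axes, while 25 probes (purple squares) lie at least 4-fold below on array 2 and at least 4-fold above on array 3.

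By rank, arrays 2 and 3 had a Spearman rho of -0.24 and arrays 1 and 2 of -0.21, and the other pairs ran from -0.07 for arrays 1 and 4 to 0.36 for arrays 1 and 3. The strongest opposition of arrays 2 and 3 was in 25 probes, chosen for it after their values were seen. Pearson r of these arrays was -0.11 without the 25, a rise that their selection makes certain in sign. They were at least 4-fold lower in the heat-shocked jar on array 2 and at least 4-fold higher in the heat-shocked jar on array 3, and 0 probes had the mirror pattern. Median log2 signals of the set were 10.02, 6.70, 11.05 and 10.36 in heat-shocked jars 1 to 4 and 10.32, 10.31, 6.69 and 9.96 in reference jars 1 to 4. All 25 were lower in heat-shocked jar 2 and in reference jar 3 than in each of the other 6 jars, 18 of them by at least 4-fold. The gaps within array 2 and within array 3 were fixed by the choice of the set. Of the 25, 13 were not well above background in 1 heat-shocked jar and 15 in 1 reference jar, which limits the size of their gaps. Fcc01013C1 (6.89) and Fcc01531 (6.86) were low in heat-shocked jar 4 too.

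**Figure D3:**
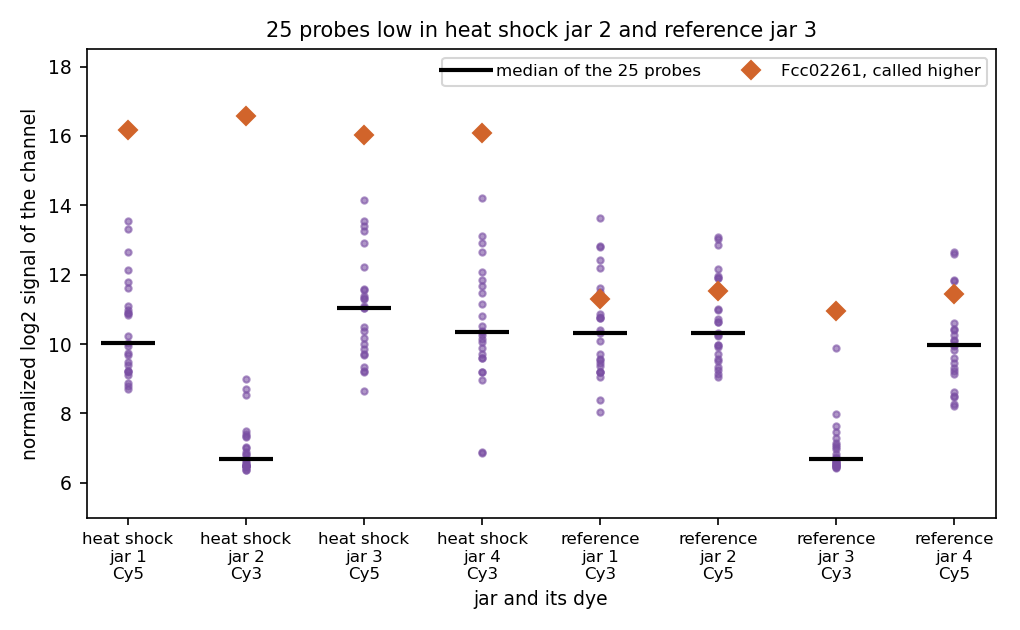
Normalized log2 signal (vertical axis) of the 25 probes of this set in each of the 8 jars (horizontal axis, with the dye of each jar), 1 purple point per probe and a black bar at their median. The medians of heat-shocked jar 2 and reference jar 3, 6.70 and 6.69, lie below those of the other 6 jars, while Fcc02261 (orange diamonds) is higher in every heat-shocked jar than in any reference jar.

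A dye effect of single probes, which cancels in the mean of both orientations, was tested with a dye column in the model. No probe passed for it (limma, 0 of 5131, smallest adjusted p = 0.196), with 796 at an unadjusted p under 0.05. That is more than the share of 0.05 that chance gives, and more than the 627 of the heat shock term in the same fit. The fit also had fewer residual degrees of freedom than the main one, so dye effects of single probes are not excluded. With median centring in place of loess, 316 probes passed for dye. With the dye column the heat shock term again called 17 probes, of which 10 were among the 17 called without it.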

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

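Chosen only after the results were seen were the tests of dye bias, exchanged labels, similar probes and a shared RNA source; no test was planned for the control spots.

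Control spots carry signal that no comparison used. The labels say that no spike-in RNA was added, yet the median signal of the 150 E1A control spots lay above the 95th percentile of the 79 negative control spots in 6 of the 8 channels. The E1A median was 76.9 against 70.3 in Cy3 of array 1, 147 against 118 in Cy5 of array 1, 107 against 101 in Cy5 of array 2, 101 against 98.4 in Cy5 of array 3, 57.3 against 56.7 in Cy3 of array 4 and 106 against 98.0 in Cy5 of array 4. On array 1, 71 of the E1A spots in Cy3 and 84 in Cy5 were well above background, against 0 to 3 per channel on the other arrays.

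The 25 probes low in heat-shocked jar 2 and reference jar 3 were weighed against technical explanations. In no other of the 28 pairs of jars was any probe at least 4-fold below all 6 remaining jars (0, against 18 in this pair), though the pair was picked for that. Both low jars carried Cy3. A dye bias of these probes that is the same on every array would raise Cy5 over Cy3 on all of them. The median loess-normalized log2 ratio of Cy5 over Cy3 was instead 3.72 and 4.30 on arrays 2 and 3 and at most 0.73 in size on arrays 1 and 4. A dye effect limited to arrays 2 and 3 was not tested. Near-identical probes are argued against by 0 members aligning to another member over 30 bases or more, as only 6 of 5131 probes align to any other; other cross-hybridisation was not tested. Exchanged labels would turn the response negative, but the 30 probes at least 2-fold higher on arrays 1 and 4 had a median of 1.31 on array 2 (exact 95% interval 0.85 to 1.60, 25 of 30 above 0) and of 2.17 on array 3 (1.70 to 2.75, 30 of 30). The interval replaced a first bound, over 90% of these probes above 0, which array 2 had missed, so both bounds were chosen after the values were seen. It takes the 30 probes as independent, which probes of 1 jar pair are not. The interval therefore does not measure the uncertainty about the labels. RNA of 1 source with a fixed makeup, present in 6 jars, stays open, since differences between those jars spread 1.35 times as much among members as among equally bright probes (0.609 to 3.19 over the pairs of jars). No biological explanation was tested, because the design names no group that parts these jars from the rest.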

How the results depend on the processing

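Slide as a random block, array weights, arrays 2 and 3 left out together and the 25-probe set left out were chosen after the data were seen. All 17 calls kept their direction under all 20 alternatives, and the median of all probes moved by less than 0.1. Each of the 17 was higher on all 4 arrays, so alternatives that use the same ratios could hardly turn a sign. The main count was 17 higher and 0 lower. Fewer passed with median centring (7, all higher), scaling between arrays (8, all higher) and slide as a fixed block (3, all higher). Without arrays 2 and 3, 0 passed (limma), with 275 at an unadjusted p under 0.05, 209 higher and 66 lower. Leaving out 1 array gave 2 to 5, all higher, from fewer samples. More passed with offset 0 (27, all higher), dim probes left out (30: 29 higher, 1 lower, of 3744 tested), a trended and robust prior (35: 34 and 1), separate channels (55: 53 and 2) and slide as a random block (47: 45 and 2). Agilent's processed ratios gave 16, of which 12 were higher and 4 lower. The authors' table gave 24, all higher. Of the 17 main calls, 17 were among those of the authors' table, the dim filter and the random block, 15 with the robust prior and with separate channels, 14 with offset 0, 10 with the dye column, 7 with Agilent's ratios and with scaling, 5 with median centring and 3 with the fixed block. For dye, 0 passed, but 316 with median centring. Except where fewer arrays or probes entered, the cause was not tested. The random block used a consensus correlation within slides of -0.29, and a negative correlation lowers the SE of a mean at a given variance. The fixed block left fewer residual degrees of freedom than the main fit. Fcc02261 stayed between 4.53 and 4.99 and lost its call without arrays 2 and 3 (adjusted p = 0.201; 2.57e-06 to 0.046 elsewhere). Fcc01918C1, a bound, had 5.72 with offset 0 and 6.25 with Agilent's ratios, above Fcc02261 in both, and lost its call without arrays 2 and 3 (3.44) and without array 1 (3.65). Signal over background limited 1097 probes, well above it in no channel. The gene list tests, and the median over probes of a gene, were not run. Each array pairs 2 jars, so the main fit is itself the paired one.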

Other observations

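The tests in this part were set out before their results were known, though after the values of the rising probes had been seen; the probes Fcc04512 and Fcc01299 and those with the Rev suffix were chosen after their values were seen.

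Probe Fcc02261, among the 17 that rose, may report a chaperone transcript. In a search of 8 protein motifs fixed beforehand, Fcc02261 was the only one of 5131 probes whose forward frames held EEVD directly before a stop codon, the C terminus of cytosolic HSP70 and HSP90 proteins, and the reverse strand had 0. Its sequence is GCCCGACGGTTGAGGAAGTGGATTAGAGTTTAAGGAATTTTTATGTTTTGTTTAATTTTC. Over 7 of the motifs, leaving out a loose small heat shock protein pattern, 2 probes held one and 1 of them rose (one-sided Fisher exact p = 0.00662, 17 rising probes). That rests on 1 probe, and a motif of 4 residues does not name a gene. The other motif-bearing probe, Fcc01103, ending in KDEL, had a log2 fold change of -0.14 (adjusted p = 0.882).

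Other properties of the rising probes were tested too. The AU-rich motif ATTTA was found in 3 of 17 (17.6%) against 19.4% of other probes (one-sided Fisher exact p = 0.668), too few to decide whether short-lived transcripts were enriched. Mean GC content was 35.6%, inside the 35.1% to 36.1% that held 95% of 10000 random sets of equally bright probes. All probes had a mean of 35.8%. The rising probes thus did not stand apart from equally bright probes in mean GC content. The range is so narrow that sets of probes hardly differ in GC content, so a GC bias over a wider range was not tested. The 4 arrays allow 8 sign patterns, too few for a share under 0.05: only 1, the real one, gave as many as 17 called probes, and the highest of the others gave 0.

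For 2 probes, picked for it, the ratio on array 2 was near 0. Fcc04512 had log2 ratios of 3.95, 0.06, 4.28 and 3.56 on arrays 1 to 4 (adjusted p = 0.408), and Fcc01299 had 2.63, -0.00, 2.95 and 1.84 (adjusted p = 0.442). The reference jar of array 2 held log2 signals of 9.33 and 10.37 for them, against 5.70 to 6.72 and 8.27 to 8.82 in the other reference jars. The gap of array 2 to the nearest other array fell just short of Dixon's 95% critical value for Fcc04512 and well short of it for Fcc01299. They were 2 of the 13 probes at least 4-fold higher on arrays 1 and 3 and at least 2-fold higher on array 4.

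Probes whose ID ends in Rev, a suffix the files do not explain, were well above background in all 8 channels in 30.1% of 83 cases, against 60.7% of the other probes (two-sided Fisher exact p = 4.2e-08). None of the 83 passed the test for heat shock, but only 17 of all 5131 probes did, so that count says little about them.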
